A study of Homo sapiens with 48 samples.

How the data were processed

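RNA from human dermal fibroblasts was measured on 48 single-colour microarrays. The starting point was the table of intensity values the authors deposited, with 1 value per probe and array. Per the labels, the fibroblasts were bought commercially, total RNA was purified on RNeasy columns, and amplified antisense RNA carrying amino allyl UTP was coupled to Cy5. The scanner, the image software and the way local background was removed are not given in the sources used here.

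The deposited intensity values were on a linear scale and not scaled between arrays. Between 4.19% and 16.3% of probes on an array were at or below 0, which is the form that subtraction of a background gives. The SD of the log2 array medians was 0.352. A rule set for this case made quantile normalization the main setting once that SD was at least 0.1. Values at or below 0 have no logarithm and were treated as missing, and no pseudocount was added in the main setting. A probe needed a value on at least 36 of the 48 arrays, which kept 27016 of 30968 probes, and 23208 of these had a value in all 24 harvests. No filter on dim probes was applied in the main setting. A probe with a mean log2 value above 8 is called bright below, and 7876 probes were bright. Intensities of at least 65400 were counted as being at the ceiling of the scale.

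Gene names came from the platform's annotation, in which 17397 probes had 1 gene name, 0 had several and 13571 had none. Names were brought up to date through a RefSeq gene table of assembly GRCh38.p14, which replaced 2645 of them. No coordinates were used. Where a gene had several probes, the probe with the highest mean over all arrays stood for it.

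The labels call the second array of each treatment and time a duplicate and do not say whether it came from another culture. The duplicates were therefore averaged, and the 24 harvests (2 treatments by 12 times) were the units of the principal tests. Differences between marinobufagenin (MBG) and untreated cells were fitted with limma 3.58.1 in R 4.3.3, with time as a block and a separate treatment coefficient at 0 h, 0.25 to 1 h, 2 to 6 h and 9 to 24 h. The mean effect weighted the last 3 windows by their numbers of times. Changes with time were fitted in the same way as means of each treatment over 0 to 1 h, 2 to 6 h and 9 to 24 h. A further fit used the 48 arrays as 24 groups of 2 and compared the treatments at each time. In that fit p-values measure only the spread between duplicate arrays, which may be technical. All p-values were two-sided and adjusted by Benjamini and Hochberg over the probes of a contrast, and a probe was called at an adjusted p under 0.05.

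A set of 23 gene lists and 7 lists of cell type markers was tested with camera in limma. The preset correlation between genes was 0.01, and each test was repeated with a correlation estimated from the data. Calls within a list were also counted with p-values adjusted over the list alone. The lists, the windows, the tests, the rule for named genes and most of the alternative settings were fixed before the data were examined. Under that rule a contrast gives up to 5 genes higher and 5 lower with the largest log2 difference among called probes with a single gene name and the same sign in arrays numbered 1 and 2. Where a direction had no call, the 3 genes with the smallest unadjusted p are given as values that did not pass. A list gives up to 4 members with the smallest unadjusted p, and 12 genes were always to be given, some of which are not reported here. The same rule was applied to the MBG time change and to the lists at single times after their values had been seen. For genes at single times the rule, also set then, took up to 5 higher and 5 lower with the largest log2 difference among called bright probes with a gene name. Genes that would show the sex of a donor were not reported.

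Alternatives changed 1 choice at a time. Those fixed beforehand were no scaling, array medians subtracted, leaving out the dimmest probes, keeping only probes with a value on all arrays, an offset on the log scale, trended and robust priors, array weights, the 48 arrays as separate samples, the replicate number as a block, the array series as a random block (with statmod 1.5.0), removal of the 0 h difference, and leaving out each array and each time. Chosen after the data were seen were bright probes only, an offset of 50, leaving out 1, 2, 3 and 24 h together, the first principal component as a covariate, tests between successive times, other scalings and left-out arrays for the lists and fixed genes called at single times, and a contrast of 0.25 to 1 h against 0 h and 9 to 24 h.

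The fits were tested on simulated data with normal errors drawn at each probe's own residual SD, in which 200 bright probes were changed by a log2 size of 1 or 2. Errors were independent between probes and held no shift shared by the probes of a harvest, so the shares do not describe data with such shifts. Over 23208 probes, the fit of the mean effect of MBG recovered 75% of probes changed by 1 and 99% of those changed by 2. For the window of 0.25 to 1 h these shares were 31% and 91%, for 2 to 6 h 6% and 66%, and for 9 to 24 h 25% and 83%. The control time change gave 56% and 96%, the MBG time change 64% and 94%, and their difference 24% and 79%. The test at a single time, simulated for 9 h over 15112 probes, gave 77% and 100%. Precision is limited by the number of harvests, and for dim probes by signal near background.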

Results

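Human dermal fibroblasts were exposed to 10 nM marinobufagenin (MBG), a bufadienolide cardiotonic steroid that inhibits the Na,K-ATPase, or left untreated. Cells of each arm were harvested at 12 times from 0 to 24 h, of which 5 lay within the first hour. Each of the 24 harvests was measured on 2 arrays, 48 in all. The summed raw intensity of an array lay between 15195100 and 77978300, with a median of 42017500, and between 3 and 278 probes of an array were at the ceiling. Duplicate arrays had Spearman correlations across bright probes of 0.958 to 0.992, and the SD between duplicates of these probes was 0.158 to 0.387 on the log2 scale. COL1A1 was at the ceiling on 34 arrays and FN1 on 47, so their differences are bounded by that ceiling.

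A large part of the variation set single harvests of both arms apart. The first principal component held 48.5% of the variance of bright probes and the second 9.20%. The score on the first component was 93.6 for MBG at 1 h, 47.5 for MBG at 3 h, 35.0 for untreated cells at 24 h and 28.0 for untreated cells at 2 h, against -25.1 to 18.3 in the other harvests. It also differed between the arms. The MBG score lay below the untreated one at 2, 9 and 24 h and above it at all other times. At 0.25 h it was 18.3 against -20.0, and at 6 h 10.3 against -21.5. The component is thus partly confounded with treatment. Each gene difference below that involves 1, 2, 3 or 24 h was therefore measured along with a harvest far out on this component.

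**Figure D1:**
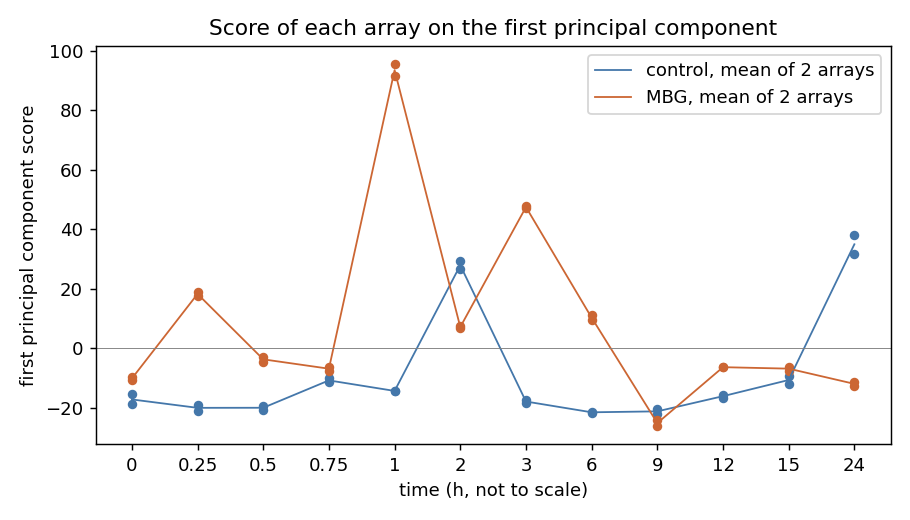
Score on the first principal component (no unit) of each of the 48 arrays against time in h, equally spaced and not to scale; points are arrays and lines join the means of 2 arrays for untreated (blue) and MBG-treated (orange) cells. Harvests with MBG at 1 h (93.6) and 3 h (47.5) and without it at 24 h (35.0) and 2 h (28.0) stand highest.

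Averaged over 0.25 to 24 h, which asks whether MBG moved a gene throughout, no gene passed the test. Those with the smallest p were dim. ADAMTS3, a procollagen-processing protease, had a log2 difference of -1.0 ± 0.13 (SE; adjusted p = 0.180), KCND2, a potassium channel subunit, one of -1.44 and THAP10 one of -1.08, while VPS13B stood at 1.44, HIP1 at 1.39 and SPIB at 1.56. Among the fixed genes the mean differences were -0.03 for ATP1B1, the beta subunit of the Na,K-ATPase, -0.29 for COL3A1, 0.04 for EGR1, 0.03 for HMOX1, 0.04 for CDKN1A, 0.18 for FOS, -0.03 for COL1A2, -0.01 for COL1A1 and -0.01 for FN1, of which COL1A2, EGR1, HMOX1 and CDKN1A changed sign on the values as deposited (0.05, -0.08, -0.22 and -0.12). The probes of COL1A2 and FOS were dim too, with mean log2 values of 5.84 and 5.53. With limma on averaged duplicates 0 of 23208 probes were called, 3079 had an unadjusted p under 0.05, and the smallest adjusted p was 0.180. Treating the 48 arrays as separate samples called 3681 probes (1185 higher, 2496 lower), the array series as a random block 7051 and array weights, whose estimation did not converge, 779, while leaving out 1, 2, 3 and 24 h called 1 lower probe.

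From 0.25 to 1 h no gene or list passed the test. EGR1, an immediate early transcription factor, differed by 0.75 ± 0.33 between MBG-treated and untreated cells (adjusted p = 0.307), the fibrillar collagen gene COL3A1 by -0.64 ± 0.32 (adjusted p = 0.343) and ATP1B3, a beta subunit of the Na,K-ATPase, by -1.46 ± 0.45 (adjusted p = 0.240). For EGR1 the same fit already gave 0.74 ± 0.66 at 0 h, before any exposure. The genes with the smallest p were C2CD4C (1.64), MAGEC3 (1.85) and TNFRSF25 (2.42) on the positive side and ADAMTS3 (-1.38), TMEM17 (-1.51) and BTRC (-1.40) on the negative side. The median was -0.18 over 13 genes of Na,K-ATPase subunits and ion transport, -0.26 over 24 p53 targets and -0.10 over 23 immediate early genes, whose list test ranked them above other genes. These 3 lists each had an adjusted p of 0.800 (0.911 with an estimated correlation). The list of DNA replication genes passed as higher once the 0 h difference was removed (median 0.36, adjusted p = 0.0101). With limma 0 probes were called and 3743 had an unadjusted p under 0.05, against 448 for the same fit at 0 h, before any exposure, where a single harvest per arm gives less precision (median SE of bright probes 0.499 against 0.249). The 48 arrays as separate samples called 5188 probes and the random block 6172, 1 probe was called without the first MBG array of 15 h, and the median of all probes moved from -0.08 to -0.25 as deposited.

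From 2 to 6 h no gene or list passed the test either. EGR1 differed by -0.62 ± 0.38 (adjusted p = 0.804) and FOS, a further immediate early gene, by -0.56 ± 0.39 (adjusted p = 0.821). RAPGEF4 (1.88), RASSF9 (1.92) and RGS9BP (2.39) had the smallest p among genes with positive differences, and TMEM17 (-1.78), THAP10 (-1.83) and PTER (-2.07) among those with negative ones. The median was -0.37 over the immediate early genes, -0.38 over the p53 targets, of which 20 of 24 were negative, and -0.30 over the Na,K-ATPase and ion transport genes, of which 12 of 13 were negative. All 3 lists had an adjusted p of 0.445 (0.882 with an estimated correlation). The DNA replication list passed as higher once the 0 h difference was removed (median 0.19, adjusted p = 0.0477). With limma 0 probes were called and 1530 had an unadjusted p under 0.05. Treating the 48 arrays as separate samples called 1069 probes, the random block 1534 and array weights 12817.

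From 9 to 24 h the collagen and matrix list had a median of 0.09 with 21 of 28 genes positive, and the mitosis list 0.12 with 21 of 28 positive, both with an adjusted p of 0.142 (0.910 with an estimated correlation). The genes of smallest p were LINC00303 (2.97), CYTIP (1.69) and MNDA (2.54) on the positive side and TC2N (-3.12), EPCAM (-2.39) and PROX1 (-2.51) on the negative, all dim and none past the test. HMOX1, a heme-degrading enzyme, differed by 0.33 ± 0.25 and CDKN1A, the cell cycle inhibitor p21, by 0.29 ± 0.28, both with an adjusted p of 1.00. With limma 0 probes were called and 727 had an unadjusted p under 0.05, and the random block called 5. A single probe was called without the first untreated array of 0.5 h, the first MBG array of 0.5 h or the second MBG array of 9 h. The mitosis list passed with the 0 h difference removed (median 0.46, adjusted p = 9.9e-04), without 1, 2, 3 and 24 h (0.21, adjusted p = 0.0187), without 15 h (0.28, adjusted p = 4.2e-05) or without 24 h (0.21, adjusted p = 0.00451), and a list passed without the second untreated array of 24 h. The collagen and matrix list passed with bright probes alone (0.06, adjusted p = 0.0483) and with the 48 arrays as separate samples (0.08, adjusted p = 0.0498).

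Markers of other cell types gave no call in any window. At 2 to 6 h, for example, medians were -0.05 for 11 keratinocyte genes, -0.07 for 8 endothelial genes (0.01 as deposited) and -0.25 for 12 fibroblast markers, with adjusted p-values of 0.788, 0.788 and 0.445.

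Compared at single times, where the error is only the spread between duplicates, the arms differed in 0 probes at 0 h, in 2670 at 0.25 h, 908 at 0.5 h, 1239 at 0.75 h, 8014 at 1 h, 3334 at 2 h, 5282 at 3 h, 1170 at 6 h, 33 at 9 h, 39 at 12 h, 47 at 15 h and 2643 at 24 h. At 0 h 1418 probes had an unadjusted p under 0.05 in limma, and trended and robust priors called 8. The same test between successive untreated harvests called 2571 probes from 1 to 2 h, 3308 from 2 to 3 h and 2846 from 15 to 24 h, and between 0 and 41 in the other 8 steps (1549 at an unadjusted p under 0.05 from 0.5 to 0.75 h, where 0 were called). Between successive MBG harvests it called 959 probes from 0 to 0.25 h, 1151 and 496 in the next steps, 8309 from 0.75 to 1 h, 7909 from 1 to 2 h, 4600 from 2 to 3 h, 2352 from 3 to 6 h, 1862 from 6 to 9 h, 205 and 36 up to 15 h and 13 from 15 to 24 h. The share of higher probes was 71.8% at 0.25 h, 17.7% at 0.5 h, 14.2% at 0.75 h, 46.1% at 1 h, 12.1% at 2 h, 57.4% at 3 h, 42.5% at 6 h, 43.6% at 12 h and 74.5% at 24 h. On the values as deposited these shares were 98.3%, 0.407%, 7.16%, 21.3%, 2.01%, 88.5%, 20%, 25% and 97.8%, and with array medians subtracted 85.0%, 2.69%, 2.60%, 26.9%, 3.56%, 50.2%, 20.3%, 25% and 88.8%. Of these, the 20% at 6 h as deposited was 1 of 5 called probes, and the 25% at 12 h was 1 of 4 under either scaling. The median of all probes moved with the scaling too, from between -0.30 (2 h) and 0.19 (3 h) to between -1.05 (0.5 h) and 0.76 (3 h) as deposited, so directions at single times are relative to the scaling used.

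**Figure D2:**
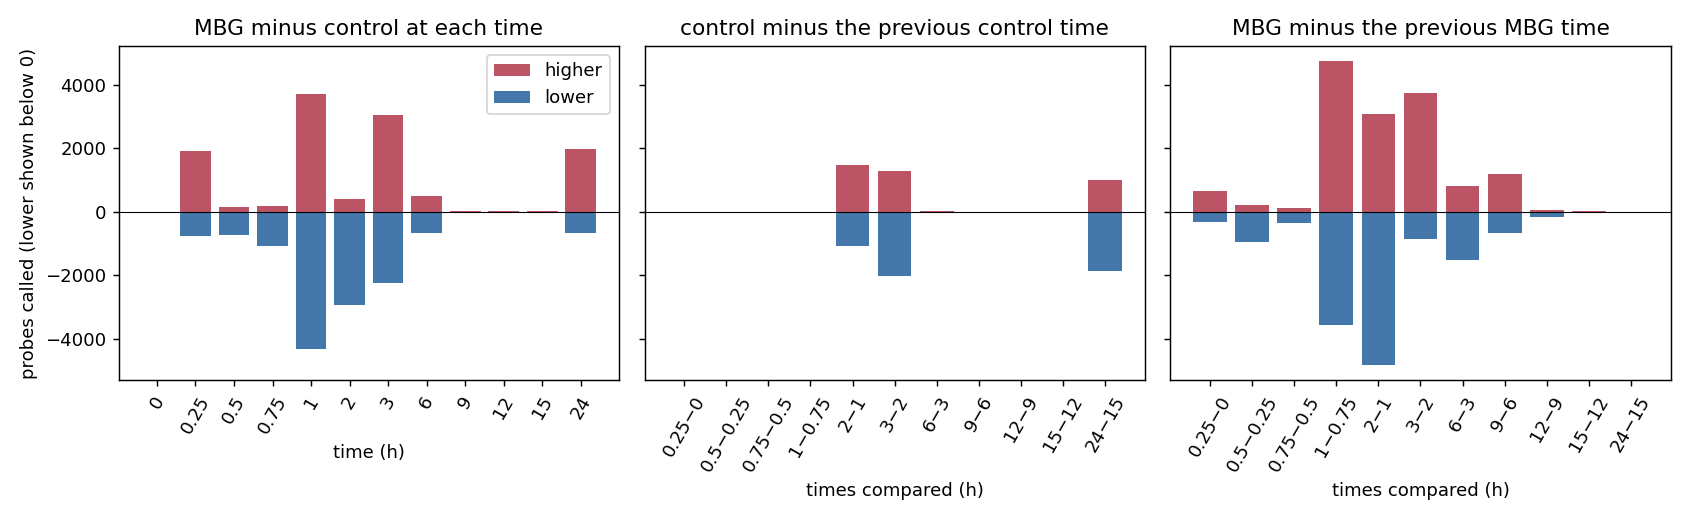
Number of probes called by limma (vertical axis) against time in h. Left, MBG minus untreated at each time, middle, each untreated harvest minus the one before it, right, each MBG harvest minus the one before it; red bars are higher probes and blue bars, drawn below 0, lower probes. The untreated steps from 1 to 2 h (2571), 2 to 3 h (3308) and 15 to 24 h (2846) stand beside 8309, 7909 and 4600 for the MBG steps up to 1, 2 and 3 h and 13 from 15 to 24 h.

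EGR1 was higher in MBG-treated cells at 1 h, by 1.09 (adjusted p = 9.8e-06), and lower at 3 h, by -1.91 (adjusted p = 1.0e-08). Both held under every scaling (-1.20 as deposited at 3 h), but EGR1 already differed by 0.74 at 0 h (adjusted p = 0.207). At 3 h untreated EGR1 stood at a log2 intensity of 14.31, against 13.21 at 2 h and 12.52 at 6 h. Its step from 3 to 6 h was itself called in limma (-1.78, adjusted p = 2.3e-06). With MBG it stood at 13.07, 12.40 and 12.71 at 2, 3 and 6 h. The 3 h difference thus includes a high untreated harvest. Untreated EGR1 also reached 14.56 at 0.75 h. The EGR1 difference between the arms was also called at 0.5 h (0.83 ± 0.17, adjusted p = 0.00915) and 0.75 h (0.73, adjusted p = 0.0129). There the direction turned on the values as deposited (-0.15 at 0.5 h) or with array medians subtracted (-0.30 at 0.75 h), and neither call held under either scaling. CDKN1A, which encodes the cell cycle inhibitor p21, differed by -0.78 at 1 h and by 1.18 at 24 h, and both directions held under every scaling. Untreated CDKN1A stood at 12.77 at 15 h and 11.91 at 24 h, and with MBG at 12.88 and 13.09. At 0.75, 1 and 2 h it stood at 13.32, 12.06 and 12.74 with MBG. Each CDKN1A difference thus includes a low harvest far out on the first component, at 24 h the untreated one. COL3A1 was lower by -2.06 ± 0.45 at 0.75 h (adjusted p = 0.00865). COL1A2, on a dim probe (mean log2 value 5.84), was higher at 3 h (1.95). HMOX1, a heme-degrading enzyme, was lower at 0.25 h (-0.88) and 1 h (-0.77), and ATP1B1 was higher at 1 h (0.54) and lower at 2 h (-0.74). The calls of HMOX1 at 0.25 h and ATP1B1 at 1 h were lost as deposited (-0.25 and 0.27, adjusted p = 0.698 and 0.754) and with array medians subtracted (-0.71 and 0.25, adjusted p = 0.0569 and 0.612). ATP1B1 at 2 h lost its call with an offset of 50 (-0.54, adjusted p = 0.0751). It stood at -1.61 as deposited and -1.19 with medians subtracted, and HMOX1 at 1 h at -1.57 and -1.58. The call held but the size moved for COL3A1 to -3.13 with medians subtracted and for COL1A2 to 1.06 with an offset of 50.

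With 1 array of a group left out, which leaves a single array there, many of these calls were lost while most differences stayed close to those of all arrays. EGR1 lost its call at 0.5 h without the first (0.82, adjusted p = 0.0739) or second (0.84, adjusted p = 0.0717) untreated or the second MBG array (0.81, adjusted p = 0.0507). At 0.75 h EGR1 lost it without the first untreated (0.56, adjusted p = 0.177) or second MBG array (0.60, adjusted p = 0.101). HMOX1 at 1 h lost it without the second untreated (-0.70, adjusted p = 0.102) or the first (-0.78, adjusted p = 0.0683) or second (-0.76, adjusted p = 0.0726) MBG array. ATP1B1 lost it at 1 h without the second untreated (0.38, adjusted p = 0.317) or either MBG array (0.63 and 0.44, adjusted p = 0.0709 and 0.231). At 2 h ATP1B1 lost it without either untreated (-0.72 and -0.76, adjusted p = 0.0975 and 0.0720) or the first MBG array (-0.54, adjusted p = 0.173). COL1A2 at 3 h lost it without the first untreated (1.42, adjusted p = 0.271) or either MBG array (2.14 and 1.76, adjusted p = 0.0882 and 0.192). The differences of HMOX1 at 0.25 h and COL3A1 at 0.75 h moved most. HMOX1 lost its call at 0.25 h without the second untreated (-0.22, adjusted p = 0.718) or the first (-0.78, adjusted p = 0.156) or second (-0.98, adjusted p = 0.0694) MBG array. Without the first untreated array it was -1.53. COL3A1 lost it without the first (-1.92, adjusted p = 0.0842) or second (-2.20, adjusted p = 0.0510) untreated or the first MBG array (-0.61, adjusted p = 0.112). Without the second MBG array it was -3.51.

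Among bright probes the largest differences at 1 h were lower MYLK (-5.98 ± 0.32), which encodes myosin light chain kinase, CAPNS1 (-5.51), CTSC (-5.17), ASPH (-5.13) and LRPAP1 (-4.81), and higher NTN1 (3.35), BEGAIN (3.03), JUNB (2.85), ZNF281 (2.73) and NOC2L (2.67). Among bright probes at 24 h MYLK was higher by 5.16 ± 0.32, BCAP31 by 4.68, GRN by 4.15 and IGFBP3 by 4.01, while 674 of the 2643 probes called at that time were lower. Bright refers to the mean over all arrays, so such a probe can lie near background in a group compared. The sizes of differences this large may then depend on background, and their order is uncertain. The 1 h comparison holds the MBG harvest and the 24 h comparison the untreated harvest that lie far out on the first component. At 0.25 h the collagen and matrix list was lower (median -0.20, 4 of 28 lower and 1 higher), with LUM (-1.28), COL6A2 (-1.03) and DCN (-0.75) among its members, but the median turned to 0.50 on the values as deposited and 0.05 with array medians subtracted, and was -0.11 without the second MBG array of that time. Its adjusted p was 7.2e-04, or 0.0137 with an estimated correlation, and 0.825 as deposited. The fibroblast markers (median -0.31, 5 of 12 lower and 0 higher, adjusted p = 7.2e-04, 0.0111 with an estimated correlation) and ribosomal proteins (-0.16, 4 of 16 lower and 0 higher, adjusted p = 0.00318, 0.0376 with an estimated correlation) passed as lower at 0.25 h too. Their medians turned to 0.34 and 0.49 as deposited, and neither list passed with array medians subtracted (-0.12 and 0.035, adjusted p = 0.284 and 0.319). The ribosomal median was -0.29 without the first untreated array of that time, and -0.31 and -0.32 without the first and second MBG array, with the call kept.

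At 12 h the interferon response list was lower with MBG (median -0.71, 5 of 25 measured lower and 0 higher, 19 of them in the test, adjusted p = 8.3e-11, 5.0e-04 with an estimated correlation) and the mitosis list higher (median 0.65, 1 of 28 measured higher, 24 of them in the test, adjusted p = 1.3e-20, 1.9e-05 with an estimated correlation). The antiviral GTPase genes MX1 (-1.95 ± 0.20, adjusted p = 1.0e-05) and MX2 (-1.67 ± 0.20) were lower, as were IFIT1 (-1.06) and IFIT3 (-1.03). Both lists kept their direction and call on the values as deposited (medians -1.24 and 0.06) and with array medians subtracted (-0.85 and 0.45), with an offset of 50 (-0.40 and 0.62), and without each array of that time. TK1, which encodes thymidine kinase, was higher by 1.30 and TPX2, a spindle assembly factor, by 1.1. By the same list test the mitosis list was also called at 0 h, before any exposure (median -0.29, adjusted p = 1.5e-05). The DNA replication list (0.18) and the TGF-beta list (0.16) passed as higher too, with adjusted p-values of 9.7e-05 and 0.00394 (0.0145 for both with an estimated correlation). Their medians turned to -0.36 and -0.41 as deposited and were 0.024 and -0.019 with array medians subtracted. The median of all probes was lower still, at -0.67 and -0.28. The list test, which compares a list with other genes, gave DNA replication adjusted p-values of 0.00145 as deposited and 1.45e-04 with array medians subtracted. For the TGF-beta list these were 0.0525 and 0.00629. In untreated cells MX1 stood at a log2 intensity of 9.97 at 12 h, against 8.01 at 9 h and 7.96 at 15 h, while the MBG harvest of 12 h stood at 8.02. The untreated steps of MX1 into and out of 12 h were themselves called in limma (1.96 and -2.01, adjusted p = 9.4e-06 and 2.9e-06). So were those of MX2 (1.78 and -1.64) and IRF7 (1.16 and -1.10). With MBG the MX1 steps were -0.11 and 0.79. The 12 h interferon difference thus includes a high untreated harvest. The count of calls at 12 h was 19 without the first untreated array of that time, and 4 either as deposited or with array medians subtracted.

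**Figure D3:**
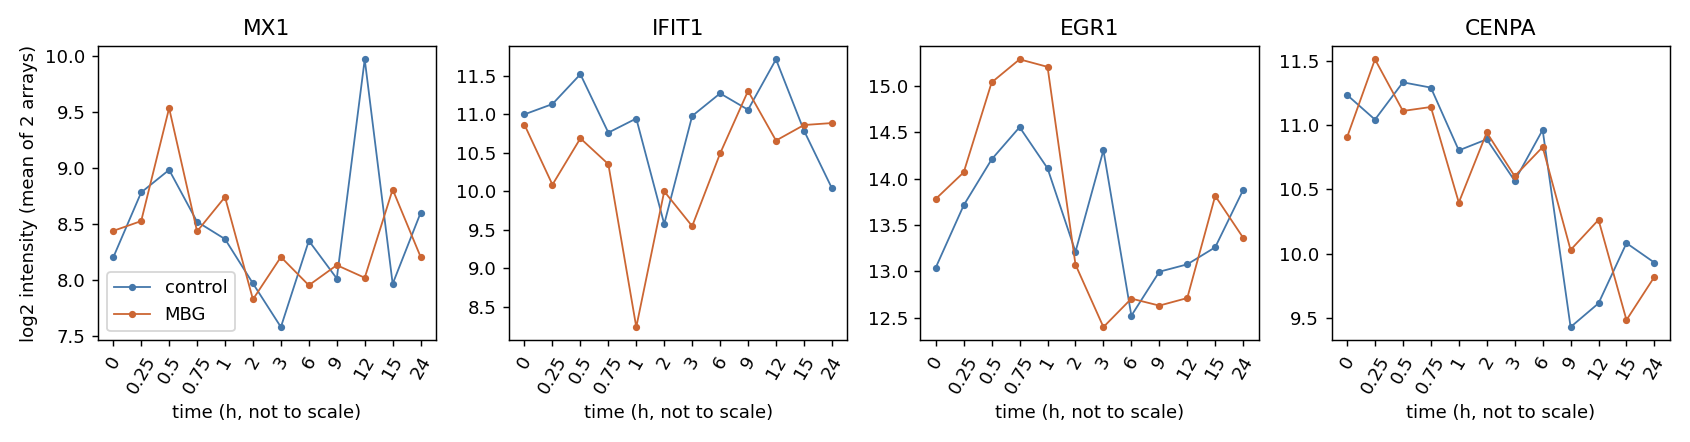
Log2 intensity after quantile normalization (vertical axes, which do not start at 0) against time in h, equally spaced and not to scale, for MX1, IFIT1, EGR1 and CENPA; each point is the mean of 2 arrays, blue untreated and orange MBG. MX1 reaches 9.97 in untreated cells at 12 h, and CENPA is lower from 9 h on in both arms.

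Counts at single times shifted with the arrays used. At 0.25 h 897 probes were called without the second untreated array, 1471 without the first MBG array and 1221 without the second. At 0.5 h the counts were 132 and 74 without the first and second untreated array, and 347 and 365 without the first and second MBG array. At 0.75 h they were 339, 292 and 1898 without the first untreated, the second untreated and the first MBG array. At 2 h the first untreated array left 1457 and the second 1747, and at 3 h the second MBG array left 3515. At 6 h the untreated arrays left 475 and 362 and the MBG arrays 352 and 667. At 9 h 14 and 10 were called without the first untreated or MBG array, 21 without either untreated array of 0.5 h, 80 without either untreated array of 3 h, and 62 without either MBG array of 1 h. At 15 h 25 were called without the second untreated and 72 without the second MBG array. At 24 h 1633 were called without the first untreated array, and 1689 and 1688 without the first and second MBG array. At 0 h, where none was called, 1 and 20 were called without the first and second untreated array, 2 and 12 without the first and second MBG array, 2 without either untreated array of 12 h and 4 without either MBG array of 0.75 h.

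In untreated cells genes of mitosis fell between 0 to 1 h and 9 to 24 h. KIF20A, a kinesin of cytokinesis, fell by 1.79 ± 0.29 on the log2 scale (adjusted p = 0.0230), CENPA, the centromeric histone H3 variant, by 1.37 ± 0.21 (adjusted p = 0.0141), ANLN, an actin-binding protein of the cleavage furrow, by 1.36 ± 0.23 (adjusted p = 0.0259), and SAPCD2 (-1.47) and KANK4 (-1.61) were lower as well. The zinc finger gene ZNF582 rose by 1.1 ± 0.21 (adjusted p = 0.0475). Of 28 mitosis genes 8 fell and 0 rose, and 24 fell when adjusted over the list alone. The cyclin genes CCNB2 (-1.24) and CCNB1 (-1.02) were among those of smallest p, the list's median was -1.15, and its adjusted p was 5.6e-36, or 0.00190 with an estimated correlation. The median of the mitosis genes, relative to untreated cells at 0 to 1 h, was -1.14 ± 0.20 (SD, n = 4 harvests) at 9 to 24 h and 0.00 ± 0.17 (SD, n = 5) at 0 to 1 h (exact permutation p = 0.00794, two-sided, 0.0159 adjusted over both arms). This permutation covered only the mitosis list, which had the smallest p of the 30 lists, and was not adjusted over them. Its 126 splits allow no smaller p, and they treat successive harvests as interchangeable.

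A further 4 lists passed in untreated cells, 3 of them lower and cholesterol synthesis higher. TGF-beta targets and myofibroblast genes had a median of -0.49, with FHL2 (-1.06), CALD1 (-0.92) and TPM1 (-0.59) of smallest p, and 0 of 19 called in either adjustment. Linker and replication-dependent histones had -0.45, with 0 of 6 called, and 1 lower, H1-2 (-0.76), adjusted over the list alone. The amino acid and ER stress response had -0.23, with SLC7A5 (-0.50) and ASNS (-0.62) and 0 of 29 called, and cholesterol synthesis 0.24, with ACAT2 (0.44) and 0 of 17 called, and 1 higher, FDFT1 (0.46), adjusted over the list alone. Their adjusted p-values were 0.0164, 0.00277, 0.0452 and 0.00498, and 0.289, 0.151, 0.348 and 0.289 with an estimated correlation. The cholesterol median turned to -0.05 on the values as deposited, where the median of all probes moved from -0.04 to -0.31, and the list did not pass there or with array medians subtracted (adjusted p = 0.101 and 0.0649). In all, limma called 23 of 23208 probes, 1 higher and 22 lower, and 1601 had an unadjusted p under 0.05. On the values as deposited or with array medians subtracted 0 were called, with 1471 and 1381 probes at an unadjusted p under 0.05, and 1 was called without 1, 2, 3 and 24 h. Leaving out 0, 0.5, 0.75 or 9 h gave 0, 12 h gave 1, 24 h gave 6, 6 h gave 9, 0.25 or 15 h gave 12 and 1 h gave 15. Without the first untreated array of 0.25 h 15 were called, without the second MBG array of 0.25 h 13 and without the second MBG array of 24 h 15. Without 0.75 h 3 lists passed.

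**Figure D4:**
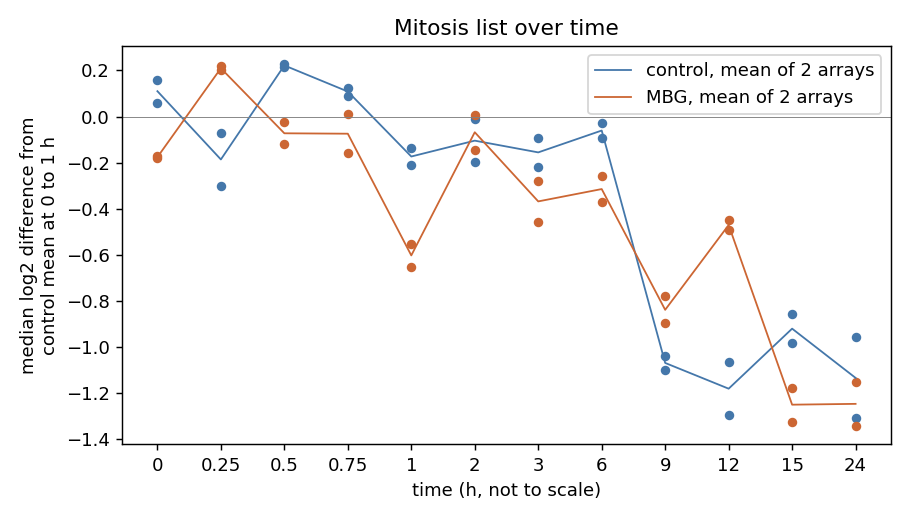
Median log2 difference of 28 mitosis genes from the untreated mean of 0 to 1 h (vertical axis) against time in h, equally spaced and not to scale; points are arrays and lines join the means of 2 arrays, blue untreated and orange MBG. Harvests of 9 to 24 h average -1.14 without and -0.98 with MBG.

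In MBG-treated cells the same period brought lower KIF2C (-1.64 ± 0.27, adjusted p = 0.0325), a microtubule-depolymerising kinesin, SAPCD2 (-1.65), SKA1 (-1.51), KIF20A (-1.50) and TPX2 (-1.45), and higher PDE7A (2.44 ± 0.43, adjusted p = 0.0325), a cAMP phosphodiesterase, PPL (1.74), which encodes periplakin, TMEM176B (1.28) and IL17RB (0.82). Of 28 mitosis genes 9 fell and 0 rose, 13 fell when adjusted over the list alone, and the median was -0.73 (adjusted p = 2.3e-14, 0.131 with an estimated correlation). The harvest medians were -0.98 ± 0.40 (SD, n = 4) and -0.13 ± 0.33 (SD, n = 5; exact permutation p = 0.0238, two-sided, 0.0238 adjusted over both arms). Here too the permutation covered the mitosis list alone, was not adjusted over the lists and treats successive harvests as interchangeable. Ribosomal proteins (median 0.27, 0 of 16 called, with RPL22 at 0.56) and fibroblast markers (0.24, 0 of 12 called, with FAP at 1.31 and DCN at 0.84) passed with adjusted p-values of 0.00312 and 0.0456, or 0.311 for both with an estimated correlation. On the values as deposited only the mitosis list passed (median -0.90), and with array medians subtracted mitosis (-0.60) and ribosomal proteins (0.38). In all, limma called 43 probes, 11 higher and 32 lower. On the values as deposited 0 were called, with 1379 at an unadjusted p under 0.05 and the median of all probes moved from -0.02 to -0.22, while 1 was called with array medians subtracted, and 1 without 1, 2, 3 and 24 h.

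The MBG count also moved with the harvests used. Without 9 or 15 h 0 probes were called, without 0.5 h 1, without 24 h 2, without 1 h 3, without 0.25 h 4, without 0.75 h 5, without 3 h 13, without 6 h 15 and without 0 h 65. Without the first untreated array of 0.25 h 13 were called, without the second of 3 h 18 and without the second MBG array of 0 h 16. The number of lists passing was 8 without 1 h and 5 without 12 h. It was 8 without the second untreated array of 0.25, 1 or 6 h or the first MBG array of 1 h. It was 7 without the first MBG array of 0.5 h or 6 h or the second of 2 h or 6 h, 6 without the second of 24 h and 5 without the first of 0.75 h.

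Both arms shared 14 lower probes, where independent lists of 22 and 32 would share 0.0303. The lists are not independent, since 1 fit gave both arms the same residual SD for a probe, so the 0.0303 is no test of the overlap. The shared probes included CENPA, CCNB1, CCNB2, CENPE, NUSAP1, PRC1 and KIF20A, along with GPRC5A, CLIC3 and NRG1. Across 7872 bright probes, which are not independent replicates, the time changes of the arms had r = -0.08 and rho = -0.10. The difference between the time changes asks whether MBG altered the course over time. It called 1 probe, PH_hs_0018436, which has no gene name here and was chosen after its value was seen. Its change was 0.97 in untreated and -2.58 in treated cells, a difference of -3.55 ± 0.50 (adjusted p = 0.0142), at a mean log2 intensity of 4.11. For the mitosis list the difference had a median of 0.33 and an adjusted p of 0.378 (0.930 with an estimated correlation). The mitosis list passed as higher on the values as deposited (0.51, adjusted p = 0.0328), with array medians subtracted (0.61, adjusted p = 0.0167), without 1, 2, 3 and 24 h (0.37, adjusted p = 0.0102), and without 0.25 h (0.50), 15 h (0.47) or 24 h (0.35). The call of PH_hs_0018436 was lost without 0, 0.25, 3, 9, 12, 15 or 24 h. It was also lost without the second untreated array of 0, 0.25, 0.5, 0.75, 6 or 9 h, the first of 12 h, the first MBG array of 0.5, 9 or 15 h or the second of 0, 0.75, 15 or 24 h.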

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

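The comparison of the 4 outlying harvests with a response to MBG alone, the brightness check of the mitosis list, the shared time course and the swaps of the arms within times for the differences between arms were chosen only after the results were seen.

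The MBG harvest of 1 h scored 93.6 on the first principal component, and the next of the 5 MBG harvests of 0 to 1 h scored 18.3. The untreated harvests of 2 and 24 h lie far out on the same component, and no MBG effect can account for those. Whether MBG moved its own pair of harvests stays open: the deviations of the MBG harvests (1 and 3 h) and the untreated ones (2 and 24 h) from the other times of their arm correlated at no less than 0.626 across bright probes, but the 4 were picked for their scores on this component, so that correlation follows in part from the choice and excludes nothing. The rank correlation of deviation with level lay between -0.139 and -0.0632 in the 4 harvests. It cannot decide on a compressed range of brightness, since quantile normalization had already made the distributions of the arrays alike. Handling and culture state of single harvests were not tested, and overall array brightness stays open, since the score and the raw upper quartile had a Spearman correlation of -0.344 over the 24 harvests (permutation p = 0.0989; Pearson r = -0.111, permutation p = 0.592, and -0.232 without the 2 farthest harvests).

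Within 0 to 1 h the MBG harvest of 1 h also stood apart in the list medians of the amino acid and ER stress response (-0.29, next -0.06), the oxidative stress and NRF2 targets (-0.77, next -0.03) and oxidative phosphorylation (-0.45, next -0.10). The untreated harvest of 24 h stood apart in the Na,K-ATPase list (-0.22, next -0.02) and in cholesterol synthesis (0.36, next 0.16). The untreated harvest of 0.5 h stood apart in collagen processing (0.11) and in histones (0.11), and the MBG harvest of 9 h in collagen processing (0.25, next 0.01). In all, 9 of 128 groups of harvests had such a value, and chance gives about 1 in 20. The time change of the probe PH_hs_0018436 differed between the arms by -3.55, by a test of the difference itself.

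The mitotic genes that were lower at 9 to 24 h in both arms may reflect culture time. The axis of the outlying harvests is argued against as the whole cause, since the weaker of the 2 arms kept a median change of -0.956 with the component's score as a covariate. Scaling is argued against likewise by a change of -0.518 or lower in each arm under each scaling. The brightness of the list is argued against, since 0% of 10000 random lists matched on mean level fell as far, and the lowest reached -0.39 in untreated and -0.40 in treated cells. Depletion of medium or crowding was not tested and stays open.

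Other groupings of the harvests bear on the counts of called probes. For the time change in untreated cells 1 of 100 splits called as many as the real 23, and that was the real split itself, with 1 in the highest other. The splits treat successive harvests of an arm as interchangeable, so a chance shift shared by neighbouring harvests is not excluded. For the MBG time change 2 of 100 called as many, the real split included, against a real count of 43, and the highest other called 122. That split sets the MBG harvests of 0.25 to 1 h against those of 0 h and 9 to 24 h and leaves the untreated harvests in their own periods. Its count is several times the real one, but the same contrast called 0 probes with both arms regrouped, so it settles no structure of the samples. For the difference of the time changes 5 of 100 splits called as many as the real 1, with 1 in the highest other, so chance is not excluded. For the mean effect of MBG and its windows the real count was 0, which every swap must reach, so the swaps decide nothing there: 100 of 100 did for the mean, with 1 in the highest other, and 8 of 8, 4 of 4 and 8 of 8 did for 0.25 to 1 h, 2 to 6 h and 9 to 24 h, with 0 in the highest other and too few swaps for a share under 0.05.

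The contrast of 0.25 to 1 h against 0 h and 9 to 24 h was weighed after it had been found among those splits. Fitted with both arms regrouped it called 0 probes in MBG-treated cells with limma (4315 at an unadjusted p under 0.05), so there were no calls for an explanation to end. With the component's score as a covariate it called 2 (3009), without the 1 h harvests 0 (2432), and in untreated cells 0 (943), which leaves the axis, the 1 h harvest and a shared time course undecided.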

How the results depend on the processing

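Chosen only after the results were seen were the tests with bright probes alone, an offset of 50, the first component as a covariate, without 1, 2, 3 and 24 h, and of single-time lists. Causes were not tested unless stated, and array weights did not converge (weights from 0.302 to 16.4), so their counts describe a degenerate weighting.

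Counts of MBG minus untreated rose where arrays replaced harvests as units, and with array weights in some windows. Fits on arrays count the 2 duplicates of a harvest as separate samples, though these may be technical, and so have more residual degrees of freedom. The random block used an estimated correlation within a series that was negative (-0.0434). The mean effect, 0 in the principal setting, gave 3681 with 48 arrays, 3595 with the replicate number as a block, 7051 with the series as a random block, 779 with array weights and 1 without 1, 2, 3 and 24 h. The window of 0.25 to 1 h gave 5188, 5071 with the replicate block and 6172, the window of 2 to 6 h 1069, 1012 and 1534 (12817 with weights), and the window of 9 to 24 h 5 with the random block. The 0 h window gave 10 with an offset of 50, 4 with weights and 1 with the component. Same-numbered arrays of the arms deviated together with correlations of -0.277 to 0.163 (median -0.0565 over 12 times), so the samples share only a number in the replicate block.

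The untreated time change, 23 in the principal setting, gave 0 in limma as deposited and with medians subtracted (1471 and 1381 at an unadjusted p under 0.05), 37 with probes on all 48 arrays, 50 with bright probes, 200 with weights, 72 with the component, 321 with 48 arrays, 302 with the replicate block, 291 with the random block and 1 without 1, 2, 3 and 24 h. The MBG time change, 43, gave 0 as deposited (1379 at an unadjusted p under 0.05), 1 with medians subtracted, 107 with bright probes, 73 with an offset of 50, 70 with trended priors, 27 with the component, 1123 with 48 arrays, 1060 with the replicate block, 1012 with the random block and 1 without 1, 2, 3 and 24 h. Their difference, 1, gave 0 in limma as deposited, without the dimmest probes, with probes on all arrays, bright probes, an offset of 50, trended priors, weights, the component, 48 arrays, either block, and without 1, 2, 3 and 24 h (507 to 4620 at an unadjusted p under 0.05, and 1725 in the principal setting).

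At single times, 0 h gave 3 without the dimmest probes, 19 with bright probes and 8 with trended priors. As deposited and with medians subtracted, 0.5 h gave 6875 and 1597, 0.75 h 335 and 9202, 2 h 7063 and 5080, 6 h 5 and 360, 9 h 0 and 0 in limma (1220 and 2314 at an unadjusted p under 0.05), 12 h 4 and 4, and 15 h 8 and 17. As deposited alone, 1 h gave 5294 and 24 h 1387. Bright probes gave 1745 at 0.5 h, 2069 at 6 h, 551 at 9 h, 237 at 12 h and 180 at 15 h. Leaving out the dimmest gave 132 at 9 h, 86 at 12 h and 118 at 15 h, trended priors 227, 76 and 131, and an offset of 50 gave 542 at 0.5 h and 84 at 9 h.

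The number of lists passing was 1 at 0.25 to 1 h and at 2 to 6 h with the 0 h difference removed, and 1 at 9 to 24 h with bright probes, the 0 h difference removed, 48 arrays, or without 1, 2, 3 and 24 h. It was 1 in untreated cells with an estimated correlation. In MBG-treated cells it was 1 as deposited, 7 without the dimmest probes, with probes on all arrays, 48 arrays or the replicate block, 8 with an offset of 50, 9 with the component, 6 without 1, 2, 3 and 24 h and 0 with an estimated correlation (mitosis median -0.73). For the difference of the time changes it was 1 as deposited, with medians subtracted, and without 1, 2, 3 and 24 h.

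Leaving out each array or time gave 0 to 20 probes at 0 h, 897 to 3383 at 0.25 h, 74 to 1066 at 0.5 h, 292 to 1898 at 0.75 h, 1457 to 3712 at 2 h, 3515 to 5577 at 3 h, 352 to 1359 at 6 h, 10 to 80 at 9 h, 19 to 49 at 12 h, 25 to 72 at 15 h and 1633 to 2899 at 24 h. The windows gave 0 to 1 (0.25 to 1 h and 9 to 24 h) and 0 to 2 (0 h), the untreated time change 0 to 26, the MBG one 0 to 65 and their difference 0 to 1. Lists passing numbered 0 to 1 at 9 to 24 h, 3 to 7 in untreated cells, 2 to 8 in MBG-treated cells and 0 to 1 for the difference.

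Directions turned at 0.75 h with medians subtracted for RBFOX2 (-0.024), TIMP1 (-0.23), SKA1 (-0.17), TRAF3IP2 (-0.17) and EGR1 (-0.30), and for HSD17B2 (0.029) without the second MBG array, against -6.75 without the first. As deposited they turned for the untreated cholesterol list (-0.050) and EGR1 at 0.5 h (-0.15). As deposited and with medians subtracted, medians turned to 0.50 and 0.046 for collagens and 0.49 and 0.035 for ribosomal proteins at 0.25 h, to -0.86 and -0.44 for ribosomal proteins and -0.70 and -0.28 for oxidative phosphorylation at 2 h, to -5.5e-06 and -0.071 for collagens at 9 h, to -0.41 and -0.019 for the TGF-beta list at 12 h, and to 0.025 and 0.082 for keratinocyte markers at 15 h. They turned for fibroblast markers at 0.25 h (0.34) and DNA replication at 12 h (-0.36) as deposited, and for ribosomal proteins at 15 h (0.0091) and collagens at 24 h (-0.10) with medians subtracted. The list test compares a list with other genes, so a turned median is not by itself a lost call. Of the other values of fixed genes at single times, 52 stayed called and 30 did not, and for lists 120 and 16. Dim probes near background limit what can be measured.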

Other observations

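The lists at single times, their scaling checks and the tests without single arrays were chosen only after the data were seen.

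At 15 h genes of NF-kappaB and inflammatory cytokines were higher with MBG (median 0.45, adjusted p = 3.9e-04, or 0.0285 with an estimated correlation). PTGS2, the inducible cyclooxygenase, was higher by 1.55 ± 0.26 (adjusted p = 0.00926), while CCL2 (0.66), NFKBIA (0.59) and TNFAIP6 (1.53) did not pass. The interferon response was higher in the same comparison (median 0.27, adjusted p = 0.00655, or 0.109 with an estimated correlation), with IFI6 at 1.32, and so opposite to its value of -0.71 at 12 h. Mitosis was lower (median -0.40, adjusted p = 7.7e-06, or 0.0285 with an estimated correlation), with KIF20A at -0.89 and CENPA at -0.60 and 0 of 28 called, against 0.65 at 12 h. DNA replication was lower as well (median -0.15, adjusted p = 0.00526, or 0.0728 with an estimated correlation). In the same comparison ribosomal proteins (-0.28, adjusted p = 0.0140, or 0.0728 with an estimated correlation) and the keratinocyte markers (-0.15, adjusted p = 0.0167, or 0.0610 with an estimated correlation) were called lower, but the ribosomal median turned to 0.0091 with array medians subtracted and the keratinocyte median to 0.025 as deposited and 0.082 with array medians subtracted. Under those 2 scalings the keratinocyte list test still gave adjusted p-values of 0.0108 and 0.0130, and the median of all probes was 0.085 and 0.14. The ribosomal call was also lost as deposited (-0.048, adjusted p = 0.613) and without the second untreated (-0.24, adjusted p = 0.0842) or first MBG array (-0.22, adjusted p = 0.0934). The keratinocyte call was lost with an offset of 50 (-0.13, adjusted p = 0.446) and without the second untreated array (-0.23, adjusted p = 0.0842), and the median was -0.48 without the first. The directions of NF-kappaB, interferon, mitosis and DNA replication held as deposited (0.56, 0.31, -0.27 and -0.11), with array medians subtracted (0.61, 0.36, -0.21 and -0.052) and with an offset of 50 (0.23, 0.14, -0.30 and -0.079), with each call kept. Without the second untreated array of 15 h NF-kappaB was 0.27 and DNA replication -0.29, without the first MBG array interferon was 0.16, and without the second MBG array DNA replication was -0.25, all still called. The difference between the 12 h and 15 h effects was not tested.

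Collagen and matrix genes at 24 h (median 0.17, adjusted p = 0.00101, or 0.0142 with an estimated correlation) included COL6A2 (3.45), LUM (2.84) and COL4A2 (1.04) among 10 of 28 called higher, but the median turned to -0.10 with array medians subtracted (adjusted p = 0.169), lost its call as deposited (0.13, adjusted p = 0.173) and was 0.28 without the first and 0.086 without the second untreated array. Fibroblast markers at 24 h (0.55) had 6 of 12 called higher, among them FAP (2.14) and PDGFRA (1.01), with an adjusted p of 0.00318 (0.0142 with an estimated correlation) that rose to 0.177 as deposited and 0.218 with array medians subtracted, and their median was 0.22 without the second untreated and 0.34 without the second MBG array. The untreated harvest of 24 h is 1 of the 4 that stand far out on the first principal component. Mitosis at 9 h was higher (0.34, adjusted p = 0.00592, or 0.290 with an estimated correlation), but only 0.20 with an offset of 50 and with array medians subtracted.

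Before any exposure, at 0 h, the mitosis list was already lower in the MBG arm (median -0.29, adjusted p = 1.5e-05, or 0.0371 with an estimated correlation). It kept that direction and call as deposited (-0.39) and with array medians subtracted (-0.50). DNA replication was lower too (-0.14, adjusted p = 0.00310, or 0.0752 with an estimated correlation), but not without the first MBG array of 0 h (-0.077, adjusted p = 0.342), and stood at -0.23 as deposited and -0.35 with array medians subtracted. Oxidative phosphorylation (-0.08, adjusted p = 0.0114, or 0.0371 with an estimated correlation) lost its call as deposited (adjusted p = 0.160) and without the first untreated (0.0910) or first MBG array (-0.034, adjusted p = 0.128) of 0 h, and was -0.14 without the second untreated array and -0.23 with array medians subtracted. Later differences of such lists between the arms may therefore hold a part that was present at the start. No MBG effect can exist at 0 h, so list tests at single times, whose error is the spread between duplicates, also pass without one. The mitosis difference did not keep its 0 h direction, with medians of 0.34 at 9 h, 0.65 at 12 h and -0.40 at 15 h.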
